A study of Mus musculus with 23 samples.

How the data were processed

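N6-methyladenine (N6-mA) in DNA was measured by DNA immunoprecipitation and sequencing in a mouse embryonic stem cell line in which Cdx2 is induced by taking doxycycline away. Per the labels' protocols, sonicated genomic DNA was ligated to adaptors, denatured, pulled down with an antibody against N6-mA and amplified by PCR. The labels place 23 samples in 13 groups, of which 5 are wild-type time points with 3 samples each, 1 is an Alkbh1 overexpression sample at day 5, and 7 are control samples of 1 label each. Island lists of 6 samples were analysed, 1 for each wild-type day and 1 for the Alkbh1 overexpression. The other 17 samples were not analysed here, so no signal of a control library stands beside the values. Whether reads of several samples were pooled for a list is not given in the sources used here.

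Per the submitters' processing notes, Bowtie2 2.3.1, SAMtools and SICER 1.1 were used with the mouse genome build mm9. SICER joins windows rich in reads into islands, and the names the authors gave the lists state a window of 200 bp, a gap of 600 bp and a false discovery rate (FDR) of 0.01. Per the labels, the input of denatured DNA served as the control in island calling. The settings of alignment and the treatment of PCR duplicates are not given in the sources used here. Each wild-type day has a list the authors named q20 unique, read here as uniquely placed reads with a mapping quality of at least 20, and a list without that name, called the all-reads list below. The Alkbh1 overexpression sample has a q20-unique list. Each deposited list gives the position of an island and a count of its reads, with no normalisation by the authors.

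Comparisons made by the authors themselves form 2 deposited tables. The first lists regions higher at day 5 than at day 0, and the second lists regions lower under Alkbh1 overexpression than in the wild type at day 5. Changes in the opposite directions were not listed in the data used here, so neither table gives a net change. In both deposited tables the authors give the raw read count of each library in a region and the same value in RPM, which is the count divided by the library total in M (mega) reads. The fold in the authors' deposited tables was found to equal the ratio of each count plus 1 divided by its library total. The p-value in the authors' deposited tables was found to be the upper tail of a Poisson distribution whose mean is the lower library's count scaled by the ratio of library totals, and an FDR accompanies it. That test takes the lower library's reads as a fixed mean and compares 2 libraries, so it holds no replicate error. Counts for identical positions showed that the decreased table rests on the q20-unique reads, with 100% of 29231 shared positions holding the same number of reads at day 5. The increased table could be matched in this way to the all-reads list at 37.2% of 13048 shared positions and to the q20-unique list at 5.28% of 6871.

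Library totals followed from the ratio of count to RPM. They were 46.0 M reads for day 5 and 54.7 M for Alkbh1 overexpression in the decreased table, and 54.6 M for day 5 and 32.0 M for day 0 in the increased table. For D3, D7 and D13 the depth is unknown, as is the q20-unique depth of D0, which limits any reading of their island numbers. The number of regions the authors tested was recovered from the ratio of FDR to p-value and was 56543 for the increased and 49287 for the decreased table.

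All computations used the 19 autosomes, X and Y, with positions counted from 1 in mm9. Islands of the mitochondrial genome were kept out of every comparison. The q20-unique lists were the main lists because all 6 samples have one. An island counted as shared when at least 1 bp lay in an island of the other list. The random level was taken from 100 random placements of the islands on their own chromosomes, with random seed 11. Placements stayed within the span that any list reached, 2581.45 Mb in all. Assembly gaps and sequence where reads cannot be placed were not left out, so this level may be low and the folds over random high. Shares carry an exact (Clopper-Pearson) 95% binomial interval. For the X share of covered sequence, the interval is that of the number of X islands, rescaled to the covered share. It leaves out variation in island width. Reads without molecular identifiers are not independent molecules and neighbouring islands are not independent, so these intervals cover counting error alone. With 1 list per group there is no spread between replicates, and no test across conditions was made. The overlap code was tested on simulated data, in which copies of 36028 day 5 islands had a known shared part. The largest gap between the true and the found shared percent was 7.1e-15 points. Separately, a direct count over D5 and D7 islands of chromosome 19 gave 0 mismatches. A randomly placed D5 list gave 0.994 times its random level against D7.

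Regions were named by a rule. It takes the 12 regions with the smallest p-value in each of the authors' deposited tables with at most 1 per 1 Mb, the 6 islands with the most reads at day 5 among those called on all 5 wild-type days, and the longest island of each list. These rules, the groups, the comparisons and the first set of alternatives were fixed before the data were examined. Alternatives were the all-reads lists, an overlap of at least 50%, only islands or regions above the median by reads or by the authors' fold, autosomes alone, placement over the whole genome, an equal list length, and another definition of the gained set. Alternatives drew 20 random placements each. Another 3 alternatives were added after the data were seen: leaving out chromosome 11, restricting the increased table to regions with a q20-unique day 5 island, and a binomial test in which the reads of both libraries vary. Because both tables use a day 5 wild-type library, 100 simulations drew Poisson reads with no difference between libraries. They started from the q20-unique day 5 islands for both comparisons. Calls were made by a binomial test with the reads of both libraries varying, not by the authors' Poisson test. The overlap found is thus only a guide to what the shared library alone produces. The summaries by 5 Mb bin were added after the data were seen. Genome features and gene lists were not analysed here, because the gene table at hand is on another assembly than mm9. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.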

Results

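N6-mA was profiled in mouse embryonic stem cells that carry a Tet-regulated Cdx2 gene. Cdx2 is a transcription factor of the trophoblast lineage, which forms the placenta, and taking doxycycline away starts its expression. The data comprised 5 wild-type days after doxycycline withdrawal (days 0, 3, 5, 7 and 13, named D0 to D13) with 3 samples each, 1 day 5 sample that overexpressed Alkbh1, and 7 control samples. Alkbh1 is an enzyme reported to remove N6-mA from DNA. Island lists of 6 samples were compared, 1 list per group, so differences between days or genotypes had no replicate check and the bracketed 95% intervals cover counting error only. Library totals were 46.0 M reads for D5 and 54.7 M for Alkbh1 overexpression among q20-unique reads, and 32.0 M for D0 and 54.6 M for D5 among the reads behind the authors' deposited table of increases, which match the all-reads lists in part. The study's title places N6-mA beside SATB1, a chromatin-organising protein, which was not measured in the data used here.

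The number and extent of N6-mA islands through differentiation came first. In the q20-unique lists of the wild-type days, islands covered most sequence at D7, with 55612 islands over 107.1 Mb, followed by D5 with 36028 islands over 95.2 Mb. D0 held 30281 islands over 51.2 Mb, D3 held 30948 over 63.0 Mb and D13 held 36465 over 65.5 Mb. Islands thus covered 1.98% of the analysed span at D0, 2.44% at D3, 3.69% at D5, 4.15% at D7 and 2.54% at D13. Island width had a median of 1600 bp at D0, 1800 bp at D3, 2400 bp at D5, 1800 bp at D7 and 1600 bp at D13.

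The island with the most reads at D5 among those called on all 5 days was on chromosome Y at 2875001 to 2902400, where overlapping islands held 7164 reads at D0, 13524 at D3, 13581 at D5, 16941 at D7 and 11205 at D13. The next was on chromosome 13 at 12961201 to 13017000 with 4170 reads at D5, and the same stretch of chromosome 13 held the longest islands of D3 (50200 bp, from 12984801), D5 (55800 bp), D7 (50400 bp, from 12984601) and, beside it, D13 (50600 bp, from 12904001). Further islands of this kind lay on chromosome 8 at 19935201 to 19950800 (3532 reads at D5), chromosome Y at 1788001 to 1793200 (1837 reads), chromosome 4 at 146889601 to 146916000 (1723 reads) and chromosome 7 at 51729001 to 51738800 (1531 reads). The longest D0 island, 70600 bp with 16547 reads, lay on chromosome 11 at 3029401 to 3100000, near the centromeric start of the assembled chromosome, and overlapped no island of the other q20-unique lists.

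The reads inside D5 islands made up 9.36% of the q20-unique library, a density 2.54 times that of reads spread evenly. In the all-reads lists the order changed. D7 (43918) and D5 (41801) had the most islands there, but D5 covered more sequence than D7 (104.1 against 101.9 Mb), and D3 had 21890 islands against 31694 at D0 and 28232 at D13. Island number depends on depth, and the totals of D3, D7 and D13 are unknown, as is the q20-unique total of D0. Among the reads behind the authors' deposited table of increases, D0 had 32.0 M and D5 54.6 M.

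**Figure D1:**
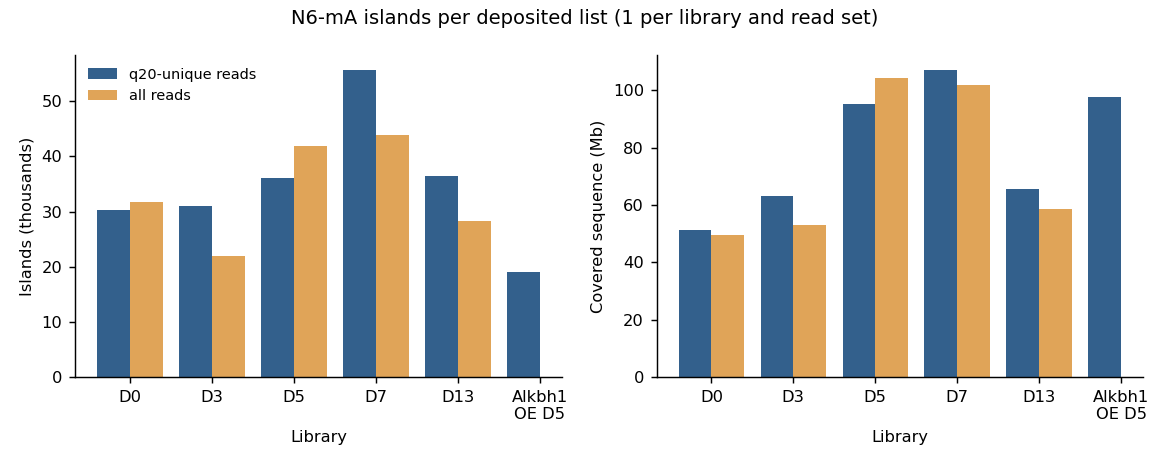
Number of islands (left, in units of 1000) and covered sequence in Mb (right) for each library, with blue bars for q20-unique lists and orange bars for all-reads lists. D7 had the most islands in both kinds of list (55612 and 43918), and an all-reads list of the Alkbh1 overexpression sample was not analysed here.

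Whether the same places were marked on successive days was asked by overlap. Of D0 islands, 36.6% (36.1 to 37.2) were also called at D3, 7.67 times the 4.77% of random placement. Of D3 islands, 50.5% (49.96 to 51.08) were called at D5, 7.24 times random. D5 and D7 had the most sequence in common: 66.6% (66.1 to 67.1) of D5 islands were called at D7, 6.46 times random, and the shared base pairs were 26.8% of their union. Of D7 islands, 37.8% (37.4 to 38.2) were called at D13, 6.73 times random. Random placement also used sequence where reads cannot be placed, so these folds may be too high.

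A core of 5205 D5 islands, 14.4%, was called on all 4 other days, where random placement gave 0.9497%. In contrast, 6105 D5 islands, 16.9%, were called on no other day, against 82.5% at random. The part of a list found on no other day was 31.2% for D0, 21.02% for D3, 31.6% for D7 and 25.8% for D13.

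The q20-unique and all-reads lists of the same day differed in many islands, and whether the choice of reads alone caused this was not tested. Of the q20-unique islands, 60.5% at D0, 39.4% at D3, 69.3% at D5, 51.3% at D7 and 45.3% at D13 were also in the all-reads list of the same day. The shared base pairs of both lists of 1 day were 32.0% of their union at D0, 25.8% at D3, 40.6% at D5, 37.3% at D7 and 29.1% at D13. Between the q20-unique lists of D5 and D7 they were 26.8%, above the value of D3 and below those of the other days.

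**Figure D2:**
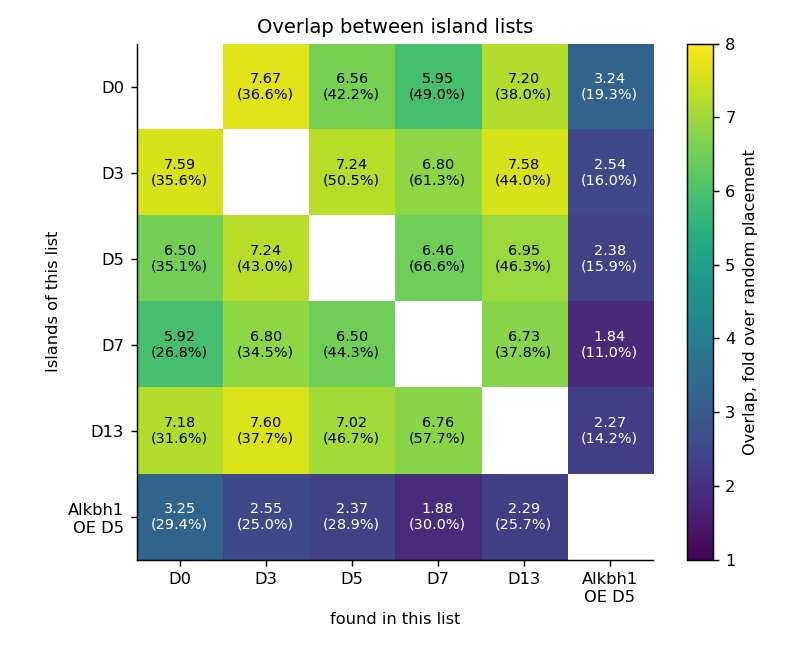
Overlap between the 6 q20-unique lists, with the list whose islands are counted on the vertical axis and the list they are sought in on the horizontal axis. Colour and upper number give the fold over 100 random placements and the lower number the percent of islands shared. Folds between wild-type days lay between 5.92 and 7.67, and those involving the Alkbh1 overexpression list between 1.84 and 3.25.

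Regions that gained N6-mA signal by D5 over D0 are given in the authors' deposited table, which holds 24072 regions over 66.2 Mb. In the authors' deposited table the median level of these regions was 1.501 RPM at D0 and 2.51 RPM at D5, with a median fold of 1.60 with an interquartile range of 1.42 to 1.87. A fold of at least 2 was reached by 4185 regions, 17.4%, and a fold of at least 3 by 363. Increases were spread over the genome, covering from 2.16% of chromosome 15 to 3.13% of chromosome 13 among autosomes, and 1.15% of X.

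By p-value, the first region of the authors' deposited table was on chromosome X at 92119201 to 92178800, a 59600 bp stretch with 97.7 RPM at D0 and 136.3 RPM at D5 (fold 1.40, p = 1.5e-163). It had islands on all 5 days in the all-reads lists and none in the q20-unique lists. The second, on chromosome 3 at 67774201 to 67774800, held 60 reads at D5 and 0 at D0, at least 11.7-fold higher when 3 reads are taken as the limit of a count of 0. This 600 bp region had a q20-unique island at D5 only and no all-reads island on any day. In the authors' deposited table, other named regions with gains above 4-fold were chromosome 12 at 25104201 to 25105800 (124 against 14 reads, fold 4.88, p = 5.72e-48) and chromosome 11 at 10690001 to 10693200 (164 against 22 reads, fold 4.20, p = 8.26e-53). Chromosome 6 at 67488201 to 67491000 rose 3.83-fold and chromosome 13 at 111100801 to 111104000 rose 3.76-fold in the authors' deposited table, and both had all-reads islands at D3, D5, D7 and D13 but not at D0. The authors' deposited table gave folds of 3.24, 3.27 and 2.97 for a trio of chromosome 14 regions at 43646201 to 43650000, 120157201 to 120160200 and 56763801 to 56767000. It gave 3.12 for chromosome 10 at 4454401 to 4457800, 2.93 for chromosome 15 at 94522401 to 94527400 and 2.69 for chromosome 9 at 55618201 to 55623400.

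Of the increased regions, 59.1% (58.5 to 59.7) overlapped a q20-unique D5 island and 10.4% (10.03 to 10.81) a D0 island, where random placement gave 7.68% and 5.30%. In the all-reads lists, which match the reads behind the authors' deposited table better, these shares were 95.5% and 14.6%. These regions were listed for being higher at D5 than at D0. A high share at D5 and a low share at D0 thus follow from the selection and are no separate support for the gain. The listed regions were 42.6% of the 56543 tested. When the reads of both libraries were allowed to vary, 12477 of the 24072 listed regions, 51.8%, passed the same FDR of 0.01, and that test too compares 2 libraries, not the conditions.

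**Figure D3:**
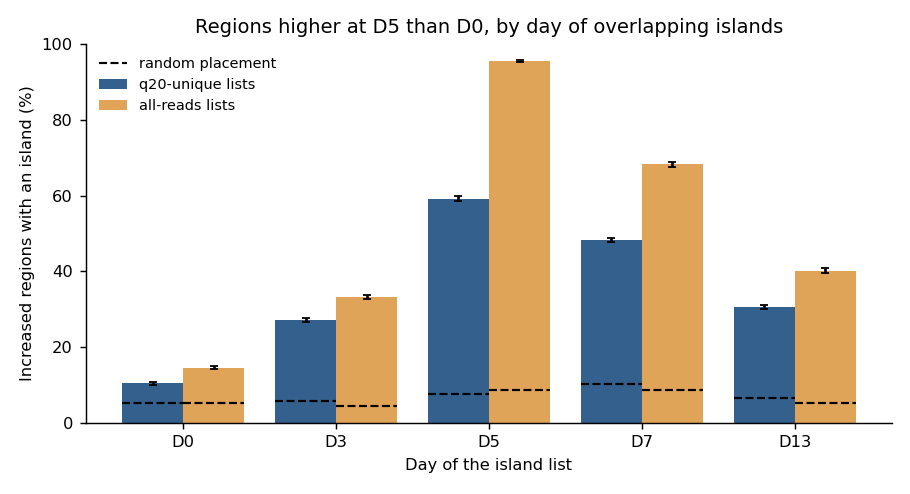
Percent of the 24072 regions of the authors' increased table that overlap an island of each wild-type day, in q20-unique lists (blue) and all-reads lists (orange). Error bars are exact 95% binomial intervals and dashed lines the mean of 100 random placements. The share was highest at D5 (59.1% and 95.5%) and lowest at D0 (10.4% and 14.6%), which follows from listing regions higher at D5 than at D0.

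Whether increased regions still had an island later was asked at D7 and D13. Of the increased regions, 48.3% (47.6 to 48.9) had a q20-unique island at D7 and 30.6% (30.0 to 31.2) at D13, against 10.1% and 6.54% at random. Only 59.1% had a q20-unique island at D5 itself, and among the 14231 that did the shares were 75.1% at D7 and 49.2% at D13. Of all D5 islands, 49.8% of the all-reads list and 66.6% of the q20-unique list had a q20-unique island at D7. At D13 these shares were 34.8% and 46.3%. Exceeding random placement is thus not particular to increased regions, and an island at D7 or D13 does not show a level above D0. At D3, 27.2% (26.6 to 27.7) of all increased regions already had an island. The chromosome 6 region at 67488201 was called in q20-unique lists at D3, D5, D7 and D13, the chromosome 14 region at 120157201 at D5, D7 and D13, and the chromosome 15 region at 94522401 at D5 and D7.

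D5 islands of the all-reads list were also split into 23083 in increased regions and 18718 others. The split itself follows the D0 level, with 10.9% against 47.6% called at D0, so differences between these sets on later days do not measure how long the gain lasted. At D13, 31.0% (30.4 to 31.6) of the islands in increased regions and 39.5% (38.8 to 40.2) of the others had a q20-unique island. At D7 the direction depended on the list: 48.6% against 51.4% with q20-unique D7 islands, and 69.8% against 61.5% with all-reads D7 islands.

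The effect of Alkbh1 overexpression on the mark was addressed at D5, for decreases only. Regions higher under overexpression were not listed in the data used here, so no net change can be read. The authors' deposited table of decreases holds 29982 regions over 81.9 Mb, with a median of 2.41 RPM in the wild type and 1.30 RPM under overexpression. Signal in the median region was thus 1.85-fold higher in the wild type in the authors' deposited table (interquartile range 1.59 to 2.22), with 11406 regions, 38.0%, at 2-fold or more and 1654 at 3-fold or more. Of the 36028 wild-type D5 islands, 83.5% (83.1 to 83.8) lay in a decreased region. This held on all autosomes but chromosome 11, with 82.3% to 91.9% of islands decreased, whereas on chromosome 11 it was 25.5% (23.8 to 27.3).

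The region with the smallest p-value in the authors' deposited table was the chromosome Y island at 2875001 to 2902400, with 295.3 RPM in the wild type and 229.4 RPM under overexpression, a wild-type level 1.29-fold higher (p = 6.37e-176). In the authors' deposited table, larger decreases were seen on chromosome 8 at 79829601 to 79832400 (198 against 60 reads, 3.88-fold), chromosome 3 at 10504201 to 10507600 (3.39-fold), chromosome 15 at 83147401 to 83150400 (3.29-fold), chromosome 6 at 7213801 to 7219200 (3.27-fold) and chromosome 14 at 52114001 to 52118000 (3.06-fold). The chromosome 3, 14 and 15 regions had wild-type islands on all 5 days and none under overexpression. The overexpression library still held 86, 137 and 99 reads in them, so the lack of an island was not a lack of reads. In the authors' deposited table, chromosome 2 lost signal at 129260201 to 129266400 (14.9 against 6.97 RPM, 2.14-fold) and at 177313601 to 177321600 (2.64-fold). Other named regions and their folds in the authors' deposited table were chromosome 12 at 8623201 to 8626800 (2.58), chromosome 1 at 7378601 to 7385600 (2.33), chromosome 7 at 30359801 to 30366200 (1.99) and chromosome 8 at 19935201 to 19950800 (1.36).

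The overexpression list held fewer but wider islands, 19110 with a median of 4200 bp over 97.8 Mb, against 36028 with a median of 2400 bp over 95.2 Mb in the wild type. Of overexpression islands, 28.9% (28.3 to 29.6) overlapped a wild-type D5 island, 2.37 times random. Of wild-type D5 islands, 15.9% (15.5 to 16.3) overlapped an overexpression island, 2.38 times random. Without chromosome 11 these values were 12.6% (12.27 to 12.99) and 3.18 times. The chromosome Y island at 2875001 overlapped no island of the overexpression list although that library held 12540 reads in it, so the absence of an island there was not an absence of reads.

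Regions lost under Alkbh1 overexpression overlapped those gained during differentiation: 43.6% (43.0 to 44.2) of decreased regions touched an increased region, against 5.24% at random. Of decreased regions, 99.97% lay on a q20-unique D5 island, and 95.5% of increased regions lay on an all-reads D5 island. An excess over random placement thus follows largely from both sets being drawn from D5 islands. Among wild-type D5 islands, 43.5% (42.9 to 44.1) of those decreased and 20.1% (19.1 to 21.2) of the others were increased. Islands in both tables numbered 13081, 1.098 times the 11918 that independent tables of these sizes give. Both tables use D5 wild-type reads. In simulated libraries with no difference, a binomial test at an FDR of 0.01 gave 0 decreased and 0.02 increased islands per simulation. That test lets the reads of both libraries vary, and q20-unique D5 reads were used for both comparisons. These counts therefore do not give the false calls of the authors' Poisson test. At an unadjusted p under 0.01 in the binomial test, 9.57% of islands passing in 1 comparison passed in the other, against 0.808% of all islands. Part of the excess may come from the shared library. Among D5 islands also called at D13, 47.5% (46.7 to 48.4) of those decreased and 19.1% (17.7 to 20.5) of the others were increased, and as both tables still rest on D5 reads there, this does not remove the shared library.

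The test behind the authors' deposited table compares 2 libraries, with 60.8% of the 49287 tested regions listed. With the reads of both libraries varying, 26234 of 29982, 87.5%, passed.

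Chromosomes differed in how much of their length the islands covered. In the Alkbh1 overexpression list 34.4% of chromosome 11 lay in islands, against a median of 2.79% on the other autosomes. These ran from 1.00% on chromosome 3 to 4.03% on chromosome 17. In wild-type D5 they ran from 2.98% to 4.61%, so the overexpression list also varied more between the other autosomes. In wild-type lists chromosome 11 was covered 1.28 to 1.54 times as much as the median of the other autosomes with q20-unique reads, and 1.09 to 1.36 times with all reads. Chromosome 11 supplied 5360 of the 19110 overexpression islands, 28.0% (27.4 to 28.7), for 4.60% of the span. The longest island of that list, 71400 bp with 3472 reads, lay there at 3239201 to 3310600. Coverage along chromosome 11 ran from 4.32% to 69.6% per 5 Mb bin.

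**Figure D4:**
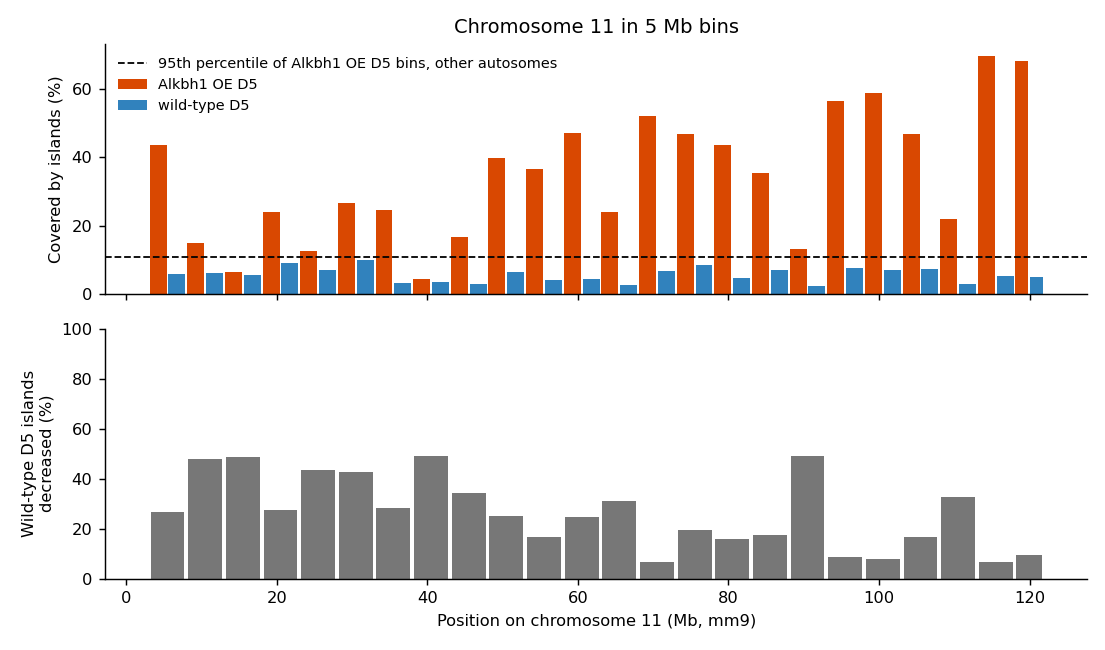
Chromosome 11 in 5 Mb bins along mm9 positions in Mb. The upper panel gives the percent of each bin covered by islands of the Alkbh1 overexpression list (orange) and of wild-type D5 (blue), with a dashed line at 10.9%, the 95th percentile of overexpression bins on the other autosomes; the lower panel gives the percent of wild-type D5 islands in a decreased region. The overexpression list lay above the line in 22 of 24 bins.

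The X chromosome was nearly free of islands in the q20-unique lists. Islands covered 0.0742% of X at D0, 0.0574% at D3, 0.0917% at D5, 0.122% at D7, 0.0567% at D13 and 0.0276% under Alkbh1 overexpression. The median autosome was covered 28.1 times as much as X at D0 and 47.3 times at D13. X made up 0.237% (0.194 to 0.286) of covered sequence at D0 and 0.158% (0.123 to 0.199) at D5, for 6.34% of the span. In the all-reads lists X coverage was 0.725% at D0 and 1.64% at D5, with the median autosome covered 2.67 and 2.56 times as much. Of the X islands in the all-reads lists, 14.4% (11.6 to 17.7) at D0 and 5.14% (3.83 to 6.74) at D5 were also in the q20-unique list, against 58.6% and 61.1% of autosomal islands.

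**Figure D5:**
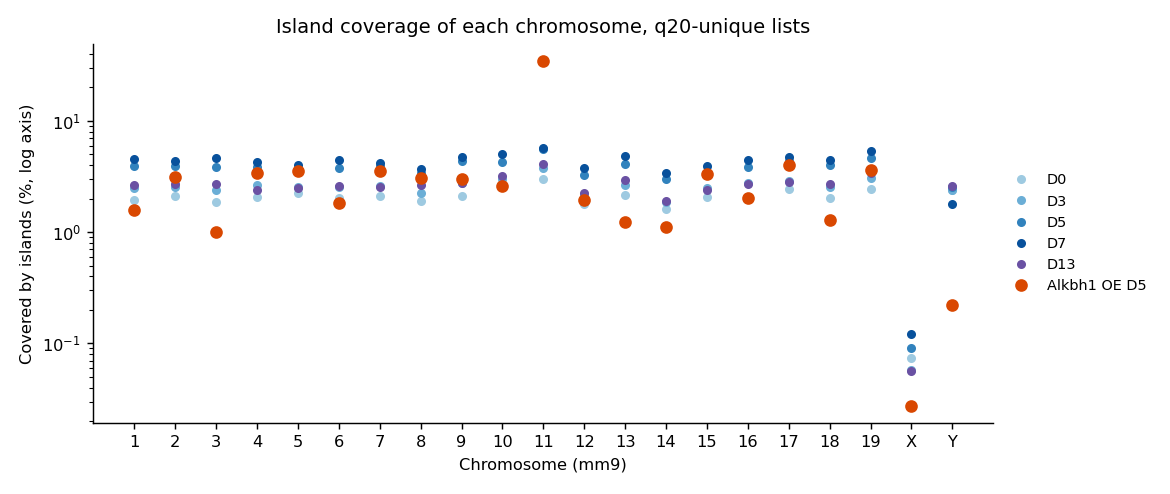
Percent of each chromosome covered by islands of the 6 q20-unique lists, on a log axis, with 1 point per list. Chromosome 11 stood apart in the Alkbh1 overexpression list (34.4%), and X was covered least in every list (0.0276% to 0.122%).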

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

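In this part, the tests of a chromosome 11 bias common to all libraries, of sequencing depth and of the calling rule were chosen only after the result was seen.

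The mitochondrial genome carried island reads in all 5 wild-type days, outside the chromosomes compared in the report and with no control library to set them against. The q20-unique islands there held 16934 reads at D0, 19627 at D3, 17852 at D5, 20626 at D7 and 19563 at D13. The all-reads islands held 27141 reads at D0, 31774 at D3, 24707 at D5, 30342 at D7 and 33174 at D13. The overexpression list has no mitochondrial island, yet in the authors' deposited table positions 10601 to 16200 held 9141 reads (167.2 RPM) in that library and 8830 (192.0 RPM) in wild-type D5, a wild-type level 1.15-fold higher (p = 2.8e-37). These reads are given because they lie outside the main comparisons and above the limit that a count of 0 allows, and no explanation was tested.

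Chromosome 11 in the Alkbh1 overexpression list is the first of 3 patterns weighed. A bias common to all libraries is argued against: chromosome 11 coverage over the other autosomes was 8.01 times the highest wild-type ratio. Extra copies of chromosome 11, a gain that mouse embryonic stem cells are known to acquire in culture, predict a rise along the whole chromosome, and 91.7% of its 5 Mb bins lay above the 95th percentile of the other autosomes, against 37.5% in wild-type D5 measured the same way. As 34.4% of chromosome 11 lay in islands and the limit was 10.9%, this share largely restates the pattern. Any cause acting along the chromosome would give it, and bins ran from 4.32% to 69.6%. The third copy, if present in every cell, would give 41.2% of D5 islands decreased on chromosome 11, and 25.5% were seen, a difference of -15.7 points that leaves this open. Extra copies in 1 culture stay a hypothesis that these values do not decide. An effect of Alkbh1 on chromosome 11 stays open and untested because only 1 overexpression library was analysed.

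The second pattern is the scarcity of X islands in q20-unique lists. Removal of reads that map to several places stays undecided: of all-reads islands, the X share also called with q20-unique reads was at most 0.247 times the autosomal share on any of the 5 days, but so few X islands were called with q20-unique reads that this ratio was bound to be low whatever removed them. A single X copy with a fixed density limit for calling predicted 3.85 times the observed X coverage at D5 (0.353% against 0.0917%), which stays between the bounds set for and against it. Over the 5 days the median autosome was covered 28.1 to 47.3 times as much as X with q20-unique reads. With all reads it was 2.14 to 2.67 times. Copy number does not change with the reads kept, so these values argue against a single copy as the only cause. Whether the calling limit acted differently in the 2 kinds of list was not tested. No mapping value was analysed here, and no biological explanation was tested.

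In the third pattern, the decrease under Alkbh1 overexpression, lower depth is argued against, since the overexpression library total was 1.19 times that of wild-type D5. Selection of regions on wild-type D5 reads predicts fewer decreases among islands called on the 4 other days, and there 78.3% were decreased against 88.6% of islands called on no other day, a ratio of 0.884 that leaves this open. The share was 90.9% on 1 other day, 89.6% on 2 and 87.5% on 3, and the median fold of decreased islands was 1.80 on all 4 other days against 1.89 on none. A different calling rule or control for the overexpression list stays undecided: the ratio of 0.398 between the shares of dense regions with an island (17.0% of 2799 for overexpression, 42.7% of 489 for D0) sets q20-unique against all-reads islands, in regions listed because each library was low there. Named regions on chromosome Y at 2875001 and chromosome 8 at 19935201 held 12540 and 3099 overexpression reads without an overexpression island. Chromosome 2 at 129260201 held 381 and had one. These single regions go with that explanation but do not decide it, as control reads there were not analysed. Removal of N6-mA by Alkbh1, which the design names, stays among the open explanations, as does a difference in pull-down between the 2 libraries, which was not tested.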

How the results depend on the processing

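Leaving out chromosome 11, restricting increased regions to those with a q20-unique D5 island, and the test with both libraries' reads varying were chosen only after the result was seen. No paired analysis was possible because the result comes from no test: the labels share replicate numbers across days, but only 1 list per group was analysed. The alternatives for genome features (3) and gene lists (3) were not run, for lack of an mm9 annotation. Of the values that answer a comparison, 36 stayed within their counting interval or within 1.5 times under an alternative and 56 moved. Among the other values 23 stayed, 14 moved and 1 reversed. With each share's counting interval this narrow, "moved" can be a small step, and the 4 folds over random between successive days stayed above 1 under each alternative run. Unknown depth at D3, D7 and D13, and of the q20-unique reads at D0, limits all comparisons of island numbers.

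Keeping islands above the median by reads left 14855 islands at D0, 15418 at D3, 17924 at D5, 27566 at D7, 18109 at D13 and 9488 under overexpression, as its construction sets. The fold over random of D0 in D3, D3 in D5, D5 in D7 and D7 in D13 became 10.4, 8.99, 7.99 and 9.04 in all-reads lists, 10.6, 10.4, 9.20 and 9.59 at 50% overlap, and 8.40, 7.81, 6.95 and 7.25 with placement over the whole genome. Above the median by reads the last 3 became 8.28, 7.98 and 8.05.

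Increased regions numbered 12026 above the median fold, 14231 with a q20-unique D5 island and 12477 with both libraries varying. Their percent with a D0 island was 14.6 in all-reads lists, 5.58 at 50% overlap, 3.10 above the median fold and 17.0 with a q20-unique D5 island. With a D5 island it was 95.5, 57.2, 57.6 and, on autosomes alone, 60.7. At D7 it was 68.2 in all-reads lists, 38.2 at 50% overlap, 61.0 for D5 islands without a D0 island and 75.1 with a q20-unique D5 island, and at D13 40.2, 21.1, 37.4 and 49.2. Increased minus other D5 islands called at D7 reversed from -2.79 to 8.39 points in all-reads lists, and the cause was not tested. At D13 it was negative with both lists (-8.44 and -6.24). Matched by island width, the difference was -3.98 and 8.30 points at D7, and -7.95 and -4.55 at D13. Over width quintiles the D13 difference ran from -15.6 to 0.907 with q20-unique lists and from -20.7 to 7.22 with all-reads lists. Its sign was thus not the same at every width.

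Decreased regions above the median fold numbered 14991. D5 islands with an overexpression island were 12.8% at 50% overlap, 15.3% at equal list length and 12.6% without chromosome 11. D5 islands decreased were 41.6% above the median fold, 86.5% at equal list length and 87.7% without chromosome 11. Decreased regions touching an increased region were 41.4% at 50% overlap and 52.5% above the median fold. The X share of covered sequence in all-reads lists was 2.39% at D0, 2.97% at D3, 2.58% at D5, 2.56% at D7 and 2.74% at D13, and by number of islands 0.353% at D0 and 0.0890% under overexpression. Apart from changes that follow from keeping fewer islands or regions, the cause was not tested.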

Other observations

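All summaries in this part were chosen only after the result was seen, and they are given as values.

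The D5 islands of the all-reads list were in an increased region more often on X, 67.2% (64.1 to 70.1) of 953, than on the autosomes, 55.0% (54.5 to 55.5) of 40794. Among autosomes the share was highest on chromosome 3 (60.2%, 58.3 to 62.0) and lowest on chromosome 5 (50.2%, 48.2 to 52.2). Increased regions per 5 Mb bin of the autosomes had a median of 44, with shorter bins at chromosome ends included, and ranged from 10 to 120 in bins of full length. The 5 fullest bins lay near the start of their chromosomes: chromosome 7 from 13022601 to 18022600 (120 regions), chromosome 1 from 3000001 to 8000000 (110), chromosome 9 from 2999801 to 7999800 (110), chromosome 3 from 13012201 to 18012200 (109) and chromosome 16 from 13015201 to 18015200 (108). The all-reads D5 islands in these bins numbered 184, 164, 152, 150 and 172, in the same order. Counts of increased regions thus also depend on how many D5 islands a bin holds.

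Increased regions followed several courses in the all-reads lists. Islands at D5, D7 and D13 but not D0 were found for 6014 regions (24.98%, 24.4 to 25.5), and 2915 of those also had one at D3. D5 was the only day with an island for 5036 regions (20.9%, 20.4 to 21.4), with a median fold of 1.67 in the authors' deposited table, close to the 1.66 of the regions called at D5, D7 and D13. In the q20-unique lists these courses held 4540 regions (18.9%) and 2054 regions (8.53%), and 8620 regions (35.8%) had an island on no day, so the numbers depend on the list.

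Across 459 bins of 5 Mb on the autosomes other than chromosome 11, the coverage by islands of wild-type days correlated with Spearman's rho of 0.663 (D0 with D7) to 0.919 (D5 with D7). Coverage by the Alkbh1 overexpression list correlated most with D0 (rho 0.716), then D3 (0.591), D13 (0.537), D5 (0.447) and D7 (0.322), so its own day was not its closest. Bins are not independent replicates, and no p-value is given. Of the 19110 overexpression islands, 49.3% (48.57 to 49.99) overlapped no island of any wild-type day, with 49.3% (48.0 to 50.7) on chromosome 11 and 49.3% (48.4 to 50.1) elsewhere. No random level was computed for these shares, and island width had a median of 5400 bp on chromosome 11 and 3800 bp elsewhere. Against wild-type D5 alone, 25.9% of the chromosome 11 islands overlapped, 1.37 times random, and 30.1% of the others, 3.14 times random.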
